A study of Mus musculus with 6 samples.

How the data were processed

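Cell suspensions of the main olfactory epithelium (MOE) from 3 female and 3 male adult wild-type mice were profiled with droplet-based 3' single-cell RNA sequencing, 1 library per animal. Per the labels, the libraries were sequenced on 2 Illumina instruments, with no label that ties an instrument to a sample. The submitters' processing notes name STAR 2.6.1, Seurat and the mouse build mm10. The counting step, the annotation and the cell filters are not given in the sources used here.

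The deposited matrices hold counts, that is, whole numbers of unique molecular identifiers (UMIs) per gene symbol and cell, with no normalization. The authors gave 3 nested matrices: a raw matrix of 72656 barcodes, a whole-epithelium matrix of 45317 cells (called MOE here) and a matrix of 20375 olfactory sensory neurons (OSN) with a receptor (called OR_OSN). Checked on the files, every barcode had the same total in each matrix that held it. The MOE cells had 1500 to 49888 UMIs and less than 10% of UMIs from mitochondrial genes. In the OR_OSN cells no second receptor gene exceeded 1 UMI, so 1 receptor per cell is a property of that selection. A deposited table of 654 receptors gave, per the authors, predicted map positions and similarities as score values of unstated unit, counts of cells, and other columns for receptor class, chromosome and genomic cluster. The other deposited files list barcodes and gene symbols.

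Genes were used by the 34572 symbols of the files, of which 1176 were receptor genes (Olfr and Taar). No coordinates were used. Analyses ran in Python 3.11.15 (numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9, matplotlib 3.10.9) and R 4.3.3 (edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0).

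Scrublet, run per library with an expected doublet rate of 0.06, called 24 of 45317 cells, 20 of them in male 1. Its score distributions gave no usable threshold. The called cells were removed as planned, and an alternative without the 6% of cells with the highest scores was added after seeing the data. The remaining cells were scaled to 10000 UMIs, log transformed and clustered on 2000 highly variable genes with 30 principal components, 15 neighbours and Leiden resolution 1. Receptor genes, sex-linked genes, mitochondrial genes and the genes of every test list were kept out of the clustering. Genes were ranked and standardised within each animal. The 37 clusters were named from 27 marker lists, by the list with the highest mean log2 ratio to the other clusters among lists with 3 markers in at least 10% of cells. A cluster stayed unnamed if another list had more markers among its 10 leading genes, or if it had few UMIs and no marker there. Names other than mature OSN also needed a mean log2 ratio of at least 1, at least 50% of markers raised 2-fold, a marker among the leading genes, no raised mature OSN markers, and 10 or more UMIs of Omp in at most 50% of cells. The marker lists were fixed in advance, but these naming rules were set after the clusters were seen. They left 16 clusters unnamed, and names such as mature OSN mean a marker profile like that cell type.

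Counts were summed per animal and cell class for the 11 classes with at least 20 cells in every animal. The main test was edgeR's quasi-likelihood test (TMM factors, filterByExpr) with Benjamini-Hochberg adjustment and a threshold of 0.05. Females were compared with males within each class. Mature with immature OSN, and OSN with a class I with those with a class II receptor, were compared within animals, with animal as a block. Receptor genes were left out of the class I and class II comparison. The standard error beside an edgeR log2 fold change is the fold change divided by the square root of its F statistic. A cell was assigned to the receptor gene with most UMIs if it had at least 3 UMIs and at least 3 times the next receptor. Receptor abundance was tested with edgeR on cells per receptor and animal, for receptors with at least 10 cells. Shares of cells were compared by two-sided exact permutation tests of 3 against 3 animals, whose smallest p is 0.1, and as an alternative with edgeR on cell numbers. Within-animal shares and levels were compared by two-sided exact sign-flip permutation tests over 6 animals, whose smallest p is 0.031.

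For receptor identity, each animal in turn was left out. The summed non-receptor profile of each receptor with at least 5 cells in that animal, as log2 of counts scaled by the library total (CPM) plus 10 over 2000 variable genes, was matched by Pearson r to profiles of receptors with at least 10 cells over the other animals. Receptor names were shuffled 1000 times per animal. For genes tied to the receptor, r between the summed females and the summed males was computed across receptors with at least 20 cells per sex, for genes with a mean of at least 20 CPM. Fixed lists were compared there with 10000 random lists matched on expression. Receptor genes with at least 1 UMI were counted per cell after thinning to 2000 UMIs. Cells with fewer UMIs were left out.

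The 25 test lists were fixed before the data were examined, as were the comparisons, tests, named-gene rule and most alternatives. They covered Y-linked genes, X-linked genes that escape inactivation, olfactory signal transduction, receptor choice, axon guidance and adhesion, dorsal or ventral zone markers, activity-regulated OSN genes, immediate early genes, heat shock, xenobiotic metabolism, odorant-binding proteins and lipocalins, steroid hormone receptors and enzymes, cholesterol synthesis, interferon response, antigen presentation, mitochondrially encoded genes, haemoglobin, neurite cytoskeleton, synaptic vesicles, cilia, the unfolded protein response, the cell cycle, coronavirus entry, trace amine-associated receptors (TAARs), and receptors studied in sex-separated mice. Lists were tested with limma's camera at a preset correlation of 0.01 and, as an alternative, with an estimated correlation. Named genes were every sex-linked list gene, members of the fixed lists, the genes past the threshold with a mean of at least 10 CPM whose groups did not overlap (up to 10 per direction and class) or that moved alike in 6 of 6 animals (up to 12 per direction), the 10 most abundant receptors, and the 20 genes most tied to the receptor. In the comparison of mature with immature OSN, only list genes are named, because other genes helped to define the clusters. Symbols without a gene name (such as Gm and Rik) are only counted unless a list holds them. Some list genes are not reported here. A group at 0 is given a floor of 3 counts over the group; floors and intervals cover counting error only.

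Alternatives were RLE factors, DESeq2 with its own size factors, no filter on low counts, the shared replicate numbers as a block, no animal block, each animal left out, called doublets kept, resolution 2, other receptor rules, other numbers of genes and cells, other pseudocounts, class II cells thinned to the class I number, and no thinning. Added after seeing the data were the alternatives on doublet scores, with unnamed OSN-like and sustentacular-like clusters scored as the class, with horizontal basal cells as background class, and without each animal for the receptor matching, tied genes and list levels. Simulated gene changes were placed only in genes above a minimum mean expression, so recovery of lower genes was not measured. On simulated data of the same size, edgeR recovered 82% of genes changed 2-fold between the sexes in mature OSN and 66.3% in immediate neuronal precursors. It recovered 90% between mature and immature OSN and 92% between class I and class II OSN. It recovered 50% of receptors changed 4-fold in abundance. False calls made up 6.77% of calls in mature OSN, 11.9% in immature OSN, 10.7% in immediate neuronal precursors and 13% in receptor abundance, against the 5% aimed at.

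The smallest sum of any tested class was 193981 UMIs, in tuft-type cells. Free RNA in droplets was not removed. Paralogous genes, such as neighbouring Olfr, Bpifb, Hbb, Obp and Mup genes, share sequence, so reads may be assigned among them with error. Barcodes outside the MOE matrix were used only for haemoglobin counts.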

Results

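The study profiled the MOE of adult mice, the tissue in which each OSN expresses mainly 1 odorant receptor, in 3 females and 3 males. Sex was the only difference between samples that the labels name. The MOE matrix held 6468, 7398 and 8329 cells in females 1 to 3 and 7464, 6114 and 9544 cells in males 1 to 3. Total UMIs in these cells were 40093487, 49761449 and 60271014 in the females and 69917321, 48613105 and 69381475 in the males. Median UMIs per cell were 4820, 4876.5 and 5574 in females and 8270.5, 6272.5 and 5513.5 in males, so male 1 was the deepest library.

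Which cell types made up the epithelium, and did the sexes differ? Mature OSN were the largest named class, at 42.9 ± 1.17% of cells in females and 43.5 ± 3.50% in males (mean ± SD, n = 3 each). Immature OSN made up 3.31 ± 0.294% and 3.85 ± 0.701%. Unnamed clusters that scored highest as mature OSN are not in these shares. With them, the mature OSN class held 3793 to 5246 cells per animal in place of 2746 to 3765. Sustentacular cells likewise numbered 804 to 1469 per animal in place of 43 to 94. Neutrophils were 4.83-fold more frequent in males (0.273 ± 0.070% against 1.32 ± 0.391%), and monocytes or dendritic cells 4.42-fold (0.0845 ± 0.0457% against 0.374 ± 0.113%). B cells averaged 4.08-fold higher in males, with overlapping groups (0.242 ± 0.154% against 0.987 ± 0.640%). Tissue macrophages stood at 1.55 ± 0.198% in females and 1.61 ± 0.117% in males. Horizontal basal cells, the reserve stem cells of the epithelium, were lower in males, at 0.661 times the female share (3.91 ± 0.620% against 2.59 ± 0.639%), and T or NK cells were 1.42-fold higher (0.294 ± 0.0301% against 0.417 ± 0.0808%).

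The groups did not overlap in 4 of 16 classes, where chance gives 10%: neutrophils, monocytes or dendritic cells, T or NK cells, and horizontal basal cells. Each had an exact permutation p of 0.1, the smallest this design allows (adjusted p = 0.4). By edgeR on cell numbers, neutrophils (log2 female minus male -2.27 ± 0.37, adjusted p = 0.00120), monocytes or dendritic cells (-2.13 ± 0.57, adjusted p = 0.0259) and B cells (-2.06 ± 0.59, adjusted p = 0.0259) passed the threshold. Neutrophils also passed in each fit that left out 1 animal. B cells missed it without male 1 (adjusted p = 0.137) or female 2 (0.260), and monocytes or dendritic cells without male 1 (0.104), female 1 (0.0839), female 3 (0.0844) or male 3 (0.0832). At resolution 2 neutrophils (adjusted p = 0.0211) and monocytes or dendritic cells (0.0218) passed by edgeR and B cells did not (0.0703). The male-to-female ratio of B cells was 2.71 without male 1 and 6.41 without female 1. Unnamed clusters held 39.0 ± 1.85% of female and 37.4 ± 2.58% of male cells.

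**Figure D1:**
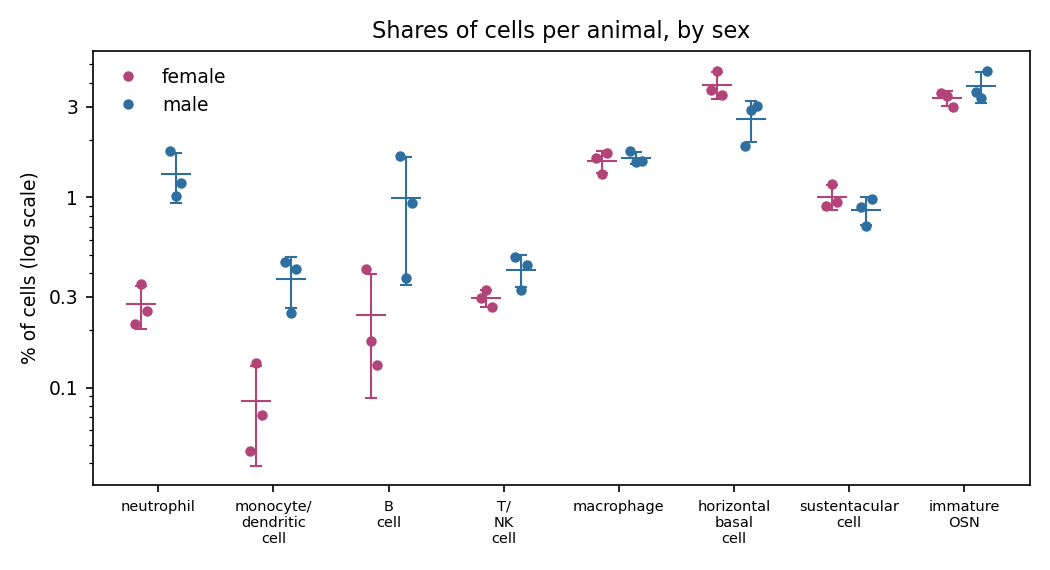
Percent of MOE cells per animal (log scale) in 8 cell classes, with 1 point per animal, the mean and the SD of 3 animals per sex. Neutrophils and monocytes or dendritic cells lie higher in all 3 males, while macrophages overlap between the sexes.

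The sex difference within each cell class was led by sex-linked genes. Xist, the RNA that silences the second X chromosome, was present in females in all 11 classes and near absent in males. Its level was at least 939.6-fold higher in female than male globose basal cells, at least 905.9-fold in ionocytes, 463.0-fold in immediate neuronal precursors, 455.0-fold in secretory cells, 413.2-fold in macrophages, 406.8-fold in ciliated cells and 238.9-fold in tuft-type cells. In mature OSN it stood at 341.0 CPM in females against 0.036 CPM in males (2 counts), and 5, 3 and 1 counts were seen in male horizontal basal cells, immature OSN and sustentacular cells. Every Y-linked gene tested (Ddx3y, Eif2s3y, Kdm5d and Uty, all broadly expressed) passed the threshold in each class, with 0 counts in females. In mature OSN their levels were at least 178.1-fold (Uty) to 1207-fold (Eif2s3y) higher in males, with a list median of at least 8.16 on the log2 scale. Tsix, the antisense partner of Xist, was also higher in female immature (15.9 against 0.107 CPM, adjusted p = 0.00032) and mature OSN (7.89 against 0.0163 CPM, adjusted p = 0.0027, both edgeR). Of 6 fits that each left out an animal, Ddx3y passed in 1 in tuft-type cells, Uty in 2 in ciliated cells and ionocytes and in 5 in horizontal basal and sustentacular cells, and Kdm5d in 3 in globose basal cells. The other Y-linked calls passed in all 6.

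Other X-linked genes known to escape inactivation had higher estimates in females, most of them short of the threshold gene by gene. In mature OSN the log2 difference was 0.67 ± 0.09 for Eif2s3x, a translation factor gene (adjusted p = 0.065), 0.69 ± 0.14 for Kdm6a (0.38), 0.39 ± 0.11 for Kdm5c (0.41), both histone demethylase genes, 0.24 ± 0.12 for the helicase gene Ddx3x (0.43) and 0.53 ± 0.10 for 5530601H04Rik (0.26). Of these, only 5530601H04Rik passed over all genes, in immature OSN (0.92 ± 0.15, edgeR adjusted p = 0.027), and it missed the threshold without female 1, 2 or 3 or male 2. With Xist, which is on the escape list, 12 values of the list passed over the 11 classes, 11 of them Xist itself, and 31 when adjusted over the list alone. The list including Xist was higher in females in 11 of 11 classes by camera, and in 10 with an estimated correlation (tuft-type cells: adjusted p = 0.0772 with an estimated correlation), so these calls rest in part on Xist. The Y-linked list, tested in 7 classes, passed in all 7 both ways.

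Past sex-linked genes, edgeR called few genes outside immediate neuronal precursors, and DESeq2 called more in several classes. Including the sex-linked genes, edgeR called 12 genes in mature OSN (3 higher in females, 9 lower), 16 in immature OSN (6 and 10), 46 in immediate neuronal precursors (38 and 8), 15 in sustentacular cells (9 and 6), 6 each in ciliated cells and macrophages, 5 each in globose basal cells, horizontal basal cells and ionocytes, and 3 each in secretory and tuft-type cells. Once the sex-linked genes were set aside, 43 genes remained in immediate neuronal precursors, 11 in sustentacular cells, 9 in immature OSN, 6 in mature OSN, 3 in macrophages, 2 in ciliated cells, 1 each in horizontal basal cells and ionocytes, and 0 in globose basal, secretory and tuft-type cells. In these last classes edgeR gave 918, 482 and 380 genes at an unadjusted p under 0.05, and DESeq2 called 20, 4 and 4 genes, sex-linked genes included. DESeq2 also called 75 genes in mature OSN (38 higher in females, 37 lower), 41 in immature OSN (21 and 20) and 50 in immediate neuronal precursors (43 and 7). It called 29 in sustentacular cells (25 and 4), 28 in horizontal basal cells (18 and 10), 13 in macrophages, 12 in ionocytes and 8 in ciliated cells. With simulated data its false calls numbered 40 in mature OSN (edgeR 13), 12 in immature OSN (23), 12 in horizontal basal cells (14) and 3 in immediate neuronal precursors (18). Of the 44 named genes outside the sex-linked ones, 4 passed in all 6 fits that left out an animal: Dlg2 and Hbb-bs in immediate neuronal precursors, Olfr181 in immature OSN and Olfr821 in sustentacular cells. Those fits also have fewer animals, and so less power. Without male 3 the number of genes rose to 340 in immediate neuronal precursors, 620 in sustentacular cells, 57 in immature OSN, 83 in ionocytes, 39 in ciliated cells, 38 in horizontal basal cells, 20 in mature OSN, 11 in globose basal cells and 7 in tuft-type cells. In macrophages it was 27 without male 2, 16 without male 1 and 10 without female 2.

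In immediate neuronal precursors, the cells between stem cell and neuron, female cells held more Dlg2, a synaptic scaffold gene (log2 1.39 ± 0.23, adjusted p = 0.0019; 92.1 ± 15.3 against 38.9 ± 9.84 CPM), and Oprm1, the mu opioid receptor gene (1.38 ± 0.26, adjusted p = 0.0108). Higher in females were also Atp5g2 (1.34 ± 0.28) and Ndufb4 (1.06 ± 0.24) of the respiratory chain, Scgb1c1 (1.31 ± 0.28), a secreted protein gene, Wdr89 (1.12 ± 0.22), the RNA polymerase subunit gene Polr2k (1.02 ± 0.19), Marf1 (1.00 ± 0.21), the splicing regulator Khdrbs3 (0.98 ± 0.23), Nrn1l (0.83 ± 0.19) and the mitochondrial gene mt-Nd3 (0.75 ± 0.18). Lower in females were haemoglobin Hbb-bs (fell by 2.82 ± 0.43), the nucleolar gene Nop56 (fell by 1.06 ± 0.24), the differentiation gene Gadd45g (fell by 1.02 ± 0.22; 112 ± 38.1 against 255.3 ± 75.6 CPM), Grasp (fell by 0.99 ± 0.20), the early response gene Ier5 (fell by 0.96 ± 0.21) and histone H1f2 (fell by 0.94 ± 0.22). Their edgeR adjusted p lay between 0.00066 (Hbb-bs) and 0.040 (H1f2). Hbb-bs, a transcript of red blood cells, was also lower over all MOE cells (12.7 against 106 CPM). Free RNA was not removed. The gland genes Bpifb9a and Bpifb9b passed the test (2.76 ± 0.56 and 2.72 ± 0.55, adjusted p = 0.0139) with overlapping groups. The groups did not overlap in 36 of the 43 genes. The 37 genes higher in females, Xist left out, had median log2 differences of 0.680 to 1.05 in the other 10 classes. Their median in precursors was 1.12, so the differences are not particular to these cells. Except Dlg2 and Hbb-bs, every gene of this paragraph missed the threshold without female 1 (Oprm1: adjusted p = 0.124). The count was 46 with all animals, 6 without female 1, 25 without male 2, 29 without female 3, 77 without male 1 and 340 without male 3.

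In immature OSN, Dlg2 was also higher in females (1.92 ± 0.31, adjusted p = 0.026; 150.8 ± 56.8 against 41.2 ± 22.3 CPM), and the heparan sulfate genes Hs3st5 (fell by 1.19 ± 0.19, adjusted p = 0.026) and Gpc1 (fell by 1.62 ± 0.27, adjusted p = 0.027) were lower, as were haemoglobins Hbb-bs (fell by 2.89 ± 0.47, adjusted p = 0.026) and Hbb-bt (fell by 3.56 ± 0.62, adjusted p = 0.043). The red-cell signal given above applies to both. The receptor genes Olfr181 (16.6 against 0.203 CPM), Olfr60 (1.57 against 21.1 CPM) and Olfr52 (0 counts in females, 65 in males) differed as well. In mature OSN, 5 of the 6 remaining genes were receptors: Olfr1176 (0.0172 against 13.1 CPM), Olfr92 (0.0216 against 3.00 CPM), Olfr644 (0.142 against 7.88 CPM) and Olfr137 (0.0389 against 2.57 CPM) were lower in females, and Olfr1198 (11.2 against 0.190 CPM) was higher. Such levels rest on single cells: Olfr1176 was the assigned receptor of 0 cells in the females and 6, 3 and 4 in the males. Without female 2, all the genes named in this paragraph but Olfr181 missed the threshold (Olfr644: adjusted p = 0.0606). In mature OSN the count was then 7; in immature OSN it was 10 without male 2 and 31 without male 1.

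In sustentacular cells, the glia-like support cells, female levels were higher for Insl6, a relaxin family gene (1.93 ± 0.35, adjusted p = 0.032), the transcription factor gene Cebpd (0.93 ± 0.18, adjusted p = 0.049) and Polr2k (0.75 ± 0.14, adjusted p = 0.042), and lower for Olfr821 (1.05 against 35.1 CPM, adjusted p = 7.36e-05), Hbb-bs (fell by 2.56 ± 0.43, adjusted p = 0.0157) and H1f2 (fell by 1.2 ± 0.20, adjusted p = 0.0153). For Hbb-bs, the red-cell signal applies here too. For Olfr821, OSN transcripts may contribute, which was not tested: 19.0% of these cells carried both a receptor and Omp at 10 or more UMIs. Without female 3, the genes named for sustentacular cells other than Olfr821 missed the threshold, and the sustentacular count was 4. This count was 6 without female 1, 9 without female 2 and 33 without male 1. At resolution 2 the count was 16, with 6 of the 15 genes shared, and of the genes named here only Olfr821 and Hbb-bs passed. With the unnamed clusters scored as sustentacular cells it was 11, with 4 of the 15 shared, and none of the named genes passed (adjusted p = 0.222 for Hbb-bs and Insl6, 0.224 for Olfr821, H1f2 and Polr2k, 0.225 for Cebpd). That widened class is mixed with OSN transcripts: in the largest cluster added, of 2586 cells, 84.5% carried both a receptor and Omp at 10 or more UMIs. Macrophages of females held less Fabp5, a fatty acid-binding protein gene (fell by 2.35 ± 0.29, adjusted p = 0.0033; 63.6 ± 3.08 against 336.1 ± 115.0 CPM), and more of the interferon-induced chemokine gene Cxcl10 (1.30 ± 0.21, adjusted p = 0.040; 460.5 ± 102.0 against 194.7 ± 26.7 CPM). Without female 3, Fabp5 had an adjusted p of 0.0637 and Cxcl10 missed the threshold too. Ionocytes held more A2ml1, a protease inhibitor gene, in females (3.17 ± 0.43, adjusted p = 0.017), which missed the threshold without male 1 or male 2. A2ml1 was also a leading gene of the unnamed cluster led by the gland genes Bpifb9a and Bpifb9b. Free RNA was not removed, and whether the A2ml1 transcripts came from ionocytes was not tested. Ciliated cells of females held more Msto1, a mitochondrial gene (2.35 ± 0.38, adjusted p = 0.047), and less keratin Krt5 (fell by 4.13 ± 0.59, adjusted p = 0.017), a basal cell marker; both missed the threshold without female 1, female 3 or male 2. Female horizontal basal cells held more Olfr728 transcript (24.8 against 1.39 CPM, adjusted p = 0.0046), a receptor that is abundant in OSN of both sexes; without male 2 its adjusted p was 0.0504.

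Of the remaining lists, none was called with an estimated correlation. With camera's preset correlation, mitochondrially encoded genes were higher in females in 10 of 11 classes (list medians 0.19 to 0.49 on the log2 scale in these 10), with 1 member past the threshold over all genes and 7 adjusted over the list alone. The smallest value over classes was adjusted p = 0.543 with an estimated correlation. Cholesterol synthesis genes were lower in females in 5 classes (medians -0.39 to -0.22 in these; 0 members by edgeR, 10 adjusted over the list alone, 6 of them in horizontal basal cells), with adjusted p = 0.279 at the smallest with an estimated correlation. Haemoglobin genes were lower in females in both classes where they could be tested (medians -2.90 in mature OSN and -1.46 in globose basal cells; adjusted p = 0.229 at the smallest with an estimated correlation). Interferon response genes were higher in females in 3 of 9 classes, with medians of 0.68 in horizontal basal cells, 0.60 in macrophages and 0.99 in secretory cells (adjusted p = 0.408 at the smallest with an estimated correlation). Other preset calls came to 4 classes for xenobiotic metabolism, 3 each for activity-regulated, signal transduction and synaptic vesicle genes, 2 each for axon guidance, immediate early, neurite cytoskeleton and unfolded protein response genes, and 1 each for cell cycle, odorant-binding and receptor choice genes. None of these was called with an estimated correlation, where the smallest adjusted p was 0.435. Antigen presentation, cilium, coronavirus entry, zone, heat shock and steroid hormone genes were called in 0 classes, and so were TAARs and the receptors studied in sex-separated mice in the 1 class with enough members. In every list called by camera, the median, the mean and the tested direction had the same sign.

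What changed as OSN matured? Mature cells held more of the machinery of odour detection and less of that of neurite growth, in 6 of 6 animals for every gene named here except where stated. All 15 tested signal transduction genes rose with maturity (list median 2.18 on the log2 scale), among them Adcy3, the adenylyl cyclase of olfactory cilia (2.97 ± 0.06; 825.2 ± 142.8 against 125.1 ± 19.0 CPM), the channel genes Cngb1 (2.66 ± 0.07) and Ano2 (2.61 ± 0.06), the exchanger gene Slc24a4 (3.15 ± 0.14) and the G protein gene Gnal (2.18 ± 0.03). Of 18 neurite cytoskeleton genes, 17 fell (median -2.60): Basp1 fell by 6.59 ± 0.11, Stmn1 fell by 6.26 ± 0.06 (72.5 ± 10.4 against 6524 ± 700.4 CPM), Tubb2b fell by 6.14 ± 0.07 and Tmsb10 fell by 4.82 ± 0.04, all genes of growing axons. The edgeR adjusted p of these genes lay between 2.34e-15 (Tmsb10) and 2.05e-09 (Slc24a4). The list genes were kept out of the clustering, but markers of odour detection and of neurite growth named the classes. The direction of these 2 lists was therefore in part set by the grouping, and their p does not allow for that.

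Single genes of metabolic and synaptic lists differed too. None of the lists in this paragraph was called by camera with an estimated correlation. Of 15 cholesterol synthesis genes, 13 fell (14 adjusted over the list alone; median -1.36), including Hmgcs1, which makes a first intermediate of the pathway (-2.75 ± 0.08). Of 11 mitochondrially encoded genes 9 rose (median 0.88), of 20 cilium genes 18 rose (median 0.60), such as Enkur (1.71 ± 0.04), and of 16 synaptic vesicle genes 12 rose and 4 fell (median 0.70), with the glutamate transporter gene Slc17a6 at 2.33 ± 0.07 and Syn2 at 2.21 ± 0.09. Activity-regulated OSN genes rose in 10 of 14 and fell in 3 (median 1.71): the calcium sensor gene S100a5 (3.67 ± 0.12) and Nrn1l (3.15 ± 0.05) rose, and the calcium-binding protein gene Calb2 fell by 2.26 ± 0.05. Of 14 receptor choice regulators, 10 fell and 1 rose (median -0.28), among them the histone demethylase gene Kdm1a (-1.43 ± 0.04; 72.0 ± 2.92 against 229.2 ± 15.5 CPM), which is known to act when a receptor is first chosen, and Emx2 (-1.42 ± 0.06). The cofactor gene Ldb1 (-0.87 ± 0.06) and the transcription factor genes Ebf1 (-0.73 ± 0.03) and Lhx2 (-0.21 ± 0.04) fell less; Lhx2 missed the threshold without a filter on low counts (adjusted p = 0.232). Axon guidance and adhesion genes went both ways, 16 of 35 up and 17 down: Epha5 (2.86 ± 0.06), Sema7a (2.41 ± 0.16) and Kirrel2 (2.26 ± 0.08) rose, while Sema3a (-3.62 ± 0.18), Pcdh11x (-3.06 ± 0.15) and Nrp1 (-1.34 ± 0.07) fell.

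In all, edgeR called 9948 of 14271 genes, 5122 higher and 4826 lower in mature OSN. By camera, 8 lists passed: signal transduction (adjusted p = 4.39e-29, and adjusted p = 0.0658 with an estimated correlation), neurite cytoskeleton (2.23e-64, and 0.0107 estimated), cholesterol synthesis (4.47e-06, and 0.411), mitochondrially encoded genes (4.47e-06, and 0.394), activity-regulated genes (1.07e-05, and 0.292), synaptic vesicle genes (0.000391, and 0.411), cilium genes (0.00106, and 0.469) and receptor choice regulators (0.00527, and 0.411). Only the neurite cytoskeleton list held with an estimated correlation. None of these p-values allows for groups that were made and named from expression in the same cells. The axon guidance list was not called (adjusted p = 0.446), nor were the other lists, of which coronavirus entry genes came nearest (adjusted p = 0.106). For axon guidance genes (median -0.07, mean 0.06) and zone markers (median -0.32, mean -0.09) camera's direction was up, and for Y-linked genes (median 0.16, mean 0.09) it was down. The change with maturity differed between the sexes for 0 genes by an edgeR interaction test, with 998 genes at an unadjusted p under 0.05. Without a low-count filter, the median of all genes moved by 0.144 on the log2 scale relative to these values, and of the 9948 genes 8889 were still called and 73 had the opposite sign.

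Odorant receptors fall into class I, an ancient family expressed in the dorsal epithelium, and the larger class II. OSN with a class I receptor held more Nqo1, a quinone reductase and known dorsal marker (3.51 ± 0.04; 823.0 ± 52.8 against 74.5 ± 15.3 CPM), and Acsm4, another dorsal marker (3.33 ± 0.05; 436.9 ± 46.5 against 44.7 ± 8.88 CPM). They held less of the nuclear factor I genes Nfix (fell by 3.51 ± 0.08; 41.3 ± 12.8 against 435.7 ± 35.8 CPM), Nfib (fell by 3.24 ± 0.12) and Nfia (fell by 2.17 ± 0.20). The largest differences named by the rule were in Tafa4, a secreted protein gene (8.56 ± 0.23; 62.5 ± 26.3 against 0.169 ± 0.0577 CPM), and the calcium-binding protein gene S100z (6.22 ± 0.25), followed by the growth factor gene Bmp3 (3.98 ± 0.28), Tmem52 (3.64 ± 0.19), the clock-related factor Bhlhe40 (3.46 ± 0.24), Adgrv1 (3.37 ± 0.25), the nuclear receptor gene Nr2f2 (3.20 ± 0.31), Aspg (3.06 ± 0.31), the cytokine signalling suppressor Socs2 (3.00 ± 0.08) and the prohormone convertase gene Pcsk2 (2.97 ± 0.17). On the class II side stood Pard3bos2 (-6.08 ± 0.25), the actin-associated gene Pdlim1 (-4.20 ± 0.11; 18 ± 12.4 against 278.7 ± 42.9 CPM), S100a10 (-4.08 ± 0.41), the adhesion gene Mdga2 (-4.07 ± 0.25), the defensin gene Defb25 (-3.82 ± 0.36), the interferon-induced gene Ifi27 (-3.73 ± 0.09), Mmgt2 (-3.58 ± 0.41), Lyl1 (-3.32 ± 0.20), the dynein gene Dnaic2 (-3.17 ± 0.34) and the polarity gene Pard3b (-3.13 ± 0.27). Each of these differed in the same direction in 6 of 6 animals, with edgeR adjusted p between 5.29e-104 (Nqo1) and 6.93e-13 (Mmgt2).

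Axon guidance genes divided between the classes, 12 of 34 higher and 9 lower in class I OSN (12 and 10 adjusted over the list alone): Robo2, a receptor for Slit repellents, was higher (1.47 ± 0.07), and the adhesion gene Ncam2 (-2.64 ± 0.12) and the semaphorin receptors Nrp2 (-2.47 ± 0.13) and Nrp1 (-1.70 ± 0.17) were lower. Of 12 zone markers, 6 were higher and 6 lower. Among these markers, Cd36 stood at 0.76 ± 0.10 (higher in 5 of 6 animals) and Cd55 at 1.04 ± 0.06. Immediate early genes, which neurons induce when active, were higher in class I OSN in 7 of 11 (8 adjusted over the list alone; median 0.58): Egr1 1.91 ± 0.11, Btg2 1.58 ± 0.12, Junb 1.32 ± 0.07 and Fos 0.87 ± 0.04 (510.0 ± 102.9 against 289.3 ± 51.8 CPM). Activity-regulated genes were higher in 3 of 13 and lower in 6 (3 and 8 adjusted over the list alone). S100a5 was higher (0.63 ± 0.03) and Cidea, a lipid droplet gene, lower (-1.67 ± 0.07). With Adcy3 at -0.25 and Ano2 at -0.41, signal transduction genes were lower in 7 of 15 and higher in 3. Of 11 mitochondrially encoded genes 5 were lower, of 17 neurite cytoskeleton genes 10 were higher and 4 lower, and of 16 synaptic vesicle genes 6 were higher and 1 lower.

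In all, edgeR called 2266 of 12942 genes, 1108 higher and 1158 lower in class I OSN, from 103 to 228 class I cells per animal. With no filter on low counts 789 were higher and 1678 lower, and by DESeq2 804 and 720. Class II cells thinned to that number gave 1222 genes, and a fit without the animal block 931. Without male 1 the count was 1651. Every gene named here passed in all 6 fits that left out an animal. By camera 6 lists passed and 0 held with an estimated correlation: immediate early (adjusted p = 2.99e-11, and adjusted p = 0.0795 with an estimated correlation), mitochondrially encoded (0.000539, and 0.290), signal transduction (0.00900, and 0.361), neurite cytoskeleton (0.00900, and 0.283), synaptic vesicle (0.0106, and 0.361) and activity-regulated genes (0.0466, and 0.361). The axon guidance and zone lists, whose members went both ways, were not called (both adjusted p = 0.781). Camera's direction was up for both, while the zone list had a median of -0.25 and a mean of -0.37, and the axon guidance list a median of 0.07 and a mean of -0.01. Of the remaining lists, unfolded protein response genes came nearest (adjusted p = 0.0552; 1 of 16 higher and 6 lower).

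**Figure D2:**
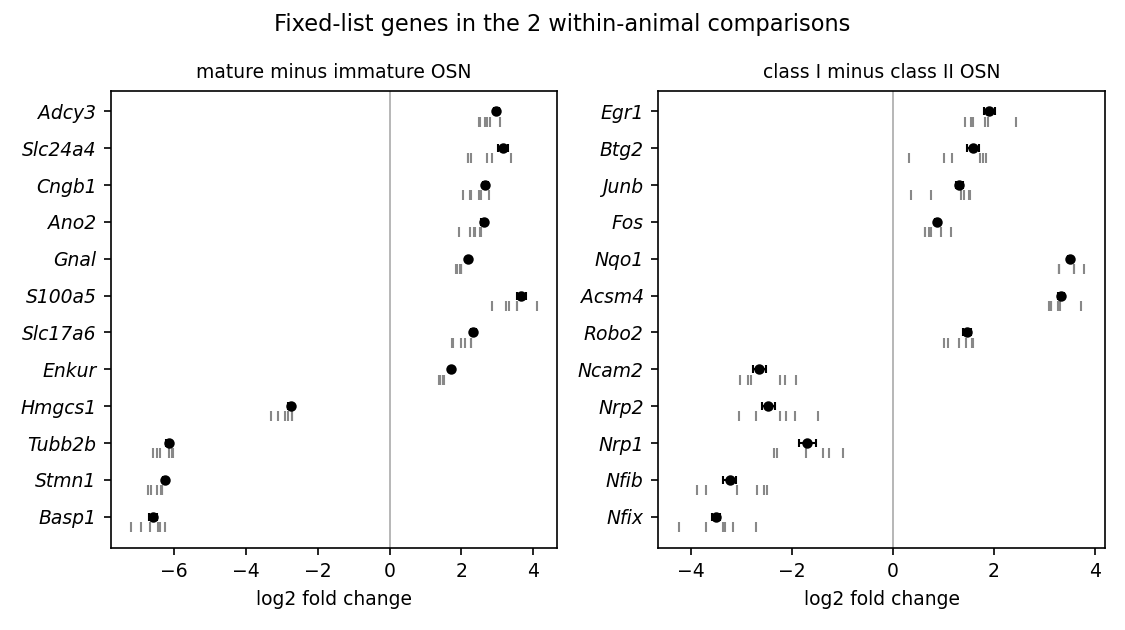
Log2 fold changes of 12 genes each in mature minus immature OSN and in class I minus class II OSN (edgeR estimate with its standard error as point and bar, and 1 tick per animal, n = 6). The ticks of the 6 animals lie on the same side of 0 for every gene shown.

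How many OSN chose each receptor, and did this depend on sex? The 20312 assigned OSN expressed 955 receptors, very unevenly: the 10 most frequent took 10.5% of cells, and the median receptor had 11 cells. Olfr1507, a well-studied class II receptor, led with 367 cells (1.77 ± 0.643% of OSN, mean ± SD of 6 animals), followed by Olfr728 (272 cells, 1.34 ± 0.240%), Olfr536 (257, 1.26 ± 0.0876%), Olfr1226 (196), Olfr1228 (182), Olfr727 (179), Olfr533 (176), Olfr1348 (174), Olfr1280 (171) and Olfr1301 (160). Class I receptors held 4.53 ± 1.79% of OSN in females and 4.48 ± 1.18% in males (exact permutation p = 1).

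No receptor differed in abundance between the sexes: of 530 tested, edgeR called 0, with 28 at an unadjusted p under 0.05, and DESeq2 called 0, with 8. The smallest adjusted p was 0.125, shared by Olfr1176 and Olfr1330 (2.05 ± 0.58; 8, 7 and 10 cells in females, 3, 2 and 1 in males). Across receptors, which are not independent replicates, the log share correlated at r = 0.784 between the pooled sexes (Spearman 0.741), and the mean r was 0.529 between animals of 1 sex and 0.516 between animals of opposite sex. The biological coefficient of variation was 21.6%, and a 4-fold change was recovered in 50% of simulated cases, so a difference of that size was missed in as many. Of the 6 receptors fixed as studied in sex-separated mice, 5 could be tested. None passed over all receptors, but 4 passed adjusted over the list alone: Olfr235 lower in females (-2.06 ± 0.64, list-adjusted p = 0.00612, adjusted p = 0.216; 0, 3 and 2 cells against 13, 3 and 7), Olfr1437 lower (-1.57 ± 0.74, 0.0416 and 0.754; 0, 1 and 4 against 5, 6 and 5), Olfr910 higher (2.97 ± 1.21, 0.0352 and 0.573; 2, 8 and 0 against 1, 0 and 0) and Olfr1295 higher (1.24 ± 0.56, 0.0416 and 0.701; 3, 12 and 6 against 3, 3 and 3), all by edgeR. Olfr1509 stood at 0.13 (0.779 and 0.984), and Olfr912 had too few cells (6). The list as a whole was not called by camera.

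Did OSN with the same receptor share a transcriptome across animals? In an animal left out, 38.6 ± 7.15% of receptors (33.8 to 51.6%, n = 6) were matched to the same receptor in the other animals from non-receptor genes alone, among 184 to 253 receptors, where chance gives 0.452%. The difference held in 6 of 6 animals (exact permutation p = 0.031, the smallest possible), and shuffled names gave a permutation p of 0.000999 in each animal, the smallest 1000 shuffles can give. The axon guidance list alone matched 39.5%, and 2000 variable genes without the axon guidance, zone and activity lists matched 33.9%. With at least 10 cells in the animal left out, 70.2 ± 9.83% were matched, among only 53 to 107 receptors, where chance gives 1.35%. Among wrong matches, 17.1 ± 3.72% fell on a receptor of the same genomic cluster, against 6.81% expected (exact permutation p = 0.031).

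Genes that varied with the receptor in both sexes were found by comparing receptors in females with receptors in males. Over 116 receptors, all class II, 530 of 6361 genes had r above 0.5, and 0 did with shuffled names. The 20 highest were led by the actin regulator Tmsb4x (r = 0.972), the creatine kinase gene Ckb (0.953), the tetraspanin gene Cd9 (0.950), Pdlim1 (0.950) and Cidea (0.949). They also held histone H2bc21 (0.947), Stoml3 (0.946), Prxl2a (0.94), the peptide gene Cartpt (0.936), Tmbim6 (0.935), Mslnl (0.934), the axon guidance receptor Nrp1 (0.933), Adam28 (0.932), Mboat1 (0.930), S100a5 (0.928), the growth factor gene Ptn (0.926), Cd55 (0.923), Cflar (0.921) and 2 without a gene name. Median r was 0.758 for axon guidance and adhesion genes against 0.118 in matched random lists, 0.744 against 0.197 for activity-regulated genes and 0.702 against 0.116 for zone markers (each permutation p = 0.0002, the smallest possible; adjusted p = 0.0012). It was 0.647 against 0.283 for signal transduction genes (adjusted permutation p = 0.0090), 0.545 against 0.227 for neurite cytoskeleton genes (0.0324) and 0.448 against 0.169 for immediate early genes (0.0474). Steroid hormone genes (0.0828), coronavirus entry genes (0.197), xenobiotic and mitochondrial genes (both 0.218) and the other lists missed the threshold. The r here is across receptors, which are not independent replicates.

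The authors' table predicts a map position for 654 receptors, 53 of class I and 601 of class II, from 59 genomic clusters. Its cell numbers equalled those counted here for 614 receptors and differed by at most 3. Its unit, axes and method are not given in the sources used here, and the positions may themselves derive from these transcriptomes. Class I receptors averaged 8.03 on the first axis and -1067 on the second, and class II receptors 14.8 and -3038. Over 310 receptors, the first axis correlated with Cidea (Spearman 0.871) and the guidance receptor gene Plxna3 (0.694), and inversely with Plxna1 (-0.792) and Robo2 (-0.757). The second correlated with Robo2 (0.646) and inversely with Nfib (-0.856), Nrp2 (-0.769) and Nfia (-0.649). These genes were picked from 46 list genes correlated with both axes, across receptors that are not independent. The table's similarity was 0.477 within a genomic cluster and 0.353 between clusters (permutation p = 0.000999, the smallest possible). It was 0.450 for pairs of class I, 0.386 for pairs of class II and 0.221 for mixed pairs, and the permutation did not allow for class. Over pairs of receptors, it correlated only weakly with the profile correlation computed here (r = 0.109).

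When do OSN settle on few receptors? After thinning to 2000 UMIs per cell, receptor genes per cell stood at 0.593 ± 0.222 in globose basal cells, 0.653 ± 0.148 in immediate neuronal precursors, 1.47 ± 0.142 in immature and 1.48 ± 0.118 in mature OSN (mean ± SD, n = 6). The background class, sustentacular cells, stood at 0.723 ± 0.139, so the levels in globose basal cells and precursors were within background. Before thinning, 21.3% of these sustentacular cells carried a receptor at 10 or more UMIs, so this background includes OSN transcripts. Cells with at least 2 receptor genes made up 12.1 ± 5.63%, 15 ± 5.72%, 39.7 ± 6.29% and 37.8 ± 6.95% in the 4 stages and 17 ± 3.85% in sustentacular cells. Immature OSN exceeded precursors by 0.812 ± 0.0639 genes per cell in 6 of 6 animals (exact permutation p = 0.031, the smallest possible; adjusted p = 0.0597 over 21 tests, which misses the threshold). Mature and immature OSN differed by 0.0139 ± 0.0541 genes per cell (exact permutation p = 0.62). Without thinning the values were 2.13 ± 0.334, 1.72 ± 0.220, 2.55 ± 0.217, 2.10 ± 0.139 and, in sustentacular cells, 2.63 ± 0.413, so that the order of OSN and background turned. Thinning left out 10 female and 9 male globose basal cells, 7 and 6 precursors, 14 and 16 immature and 229 and 260 mature OSN.

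**Figure D3:**
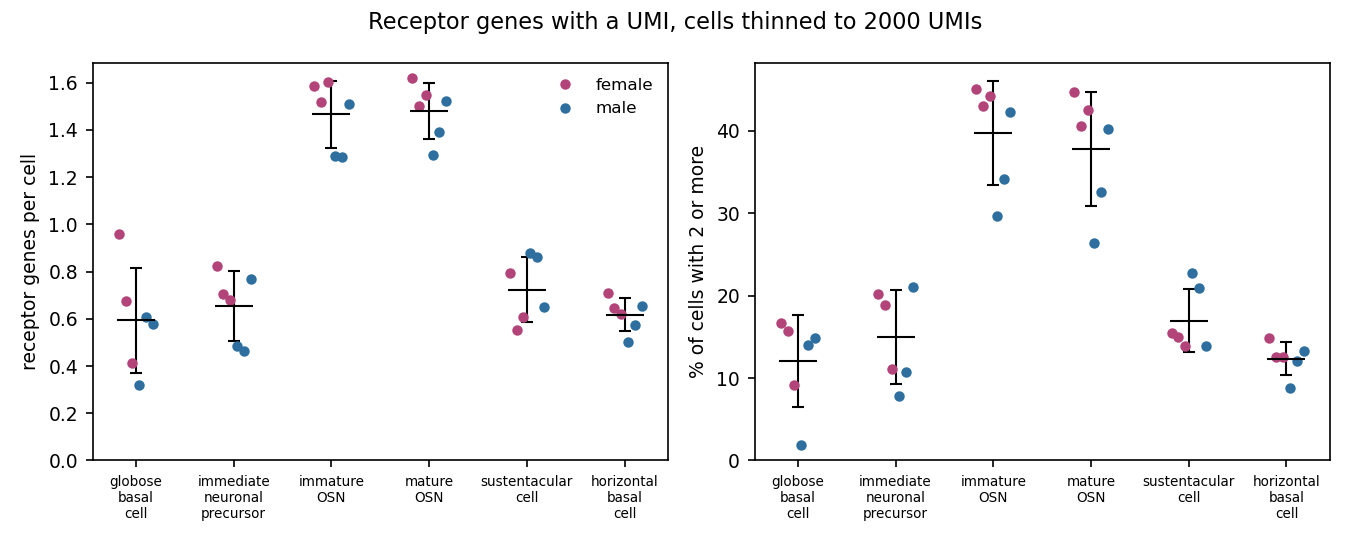
Receptor genes with a UMI per cell (left) and percent of cells with 2 or more (right) after thinning to 2000 UMIs, by class, with 1 point per animal and the mean and SD of 6 animals. Globose basal cells and precursors lie at the level of sustentacular and horizontal basal cells, and immature and mature OSN lie above.

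Where were genes of drug metabolism and of coronavirus entry highest? Among the 11 named classes tested, sustentacular cells were highest for 12 of 26 xenobiotic genes: Cyp2a5, a cytochrome P450, reached 31588 ± 3132 CPM there against 176 ± 41 CPM in mature OSN, Ugt2a2 6850.2 ± 511.8, Cyp2f2 2819 ± 239, the P450 reductase gene Por 2400.2 ± 247, Cyp1a2 1940.3 ± 136 and Aox2 1033 ± 44.5 CPM (n = 6). Horizontal basal cells were highest for the glutathione transferase Gstm1 (2016 ± 672 CPM), the oestrogen sulfotransferase Sult1e1 (557 ± 52.1) and Fmo2 (415 ± 58.3), ciliated cells for Cyp4b1 (462.7 ± 110.3) and Cyp2b10 (126 ± 16), and secretory cells for Aldh3a1 (263 ± 60.8) and Fmo1 (182 ± 30.9). Unnamed clusters were not ranked, although they held most cells that scored highest as sustentacular cells. Gstm1 was higher in 2 unnamed clusters (5453 ± 870 and 3090 ± 649 CPM) than in horizontal basal cells. At resolution 2, unnamed clusters of 2391 and 1128 cells scored highest as sustentacular cells. Gstm1 and Cyp4b1 were among the leading genes of both, so these genes are not particular to basal or ciliated cells. In 24 of 26 xenobiotic genes the highest class exceeded mature OSN (exact permutation adjusted p = 0.0326). That class was chosen as the highest in the same animals, and the p does not allow for the choice. The exceptions were Ces1a (adjusted p = 0.25) and Sult1d1, highest in mature OSN themselves (866 ± 103 CPM).

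Each coronavirus entry gene named here was higher in another class than in mature OSN, in 6 of 6 animals (exact permutation adjusted p = 0.031, the smallest possible, again without allowance for the choice of the highest of the named classes). The protease gene Tmprss2 reached 141 ± 18.1 CPM in sustentacular cells against 1.55 in mature OSN, Dpp4 9.27 ± 3.72 CPM there, Tmprss4 56.3 ± 26.5 in globose basal cells, Ctsl 1100.3 ± 88.6 in horizontal basal cells, Ctsb 1516 ± 356 in macrophages, Furin 61.0 ± 17.5 in ciliated cells, Nrp1 125 ± 28.9 in immature OSN, Bsg 1702 ± 137 in ionocytes and Anpep 20.4 ± 5.03 in secretory cells. All 10 tested odorant-binding proteins and lipocalins also averaged highest outside mature OSN, but 0 passed the same test (smallest adjusted p = 0.104, with 3 at an unadjusted p under 0.05). With 10 genes adjusted together, 3 genes at the smallest possible p cannot pass, so this is no evidence of equal levels. Their levels varied widely between animals, with Obp1a at 103 ± 137 CPM in macrophages. An unnamed cluster of 1672 cells, with Obp2a and Mup4 among its leading genes, was not ranked. Free RNA adds to every class, so low levels are upper bounds.

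**Figure D4:**
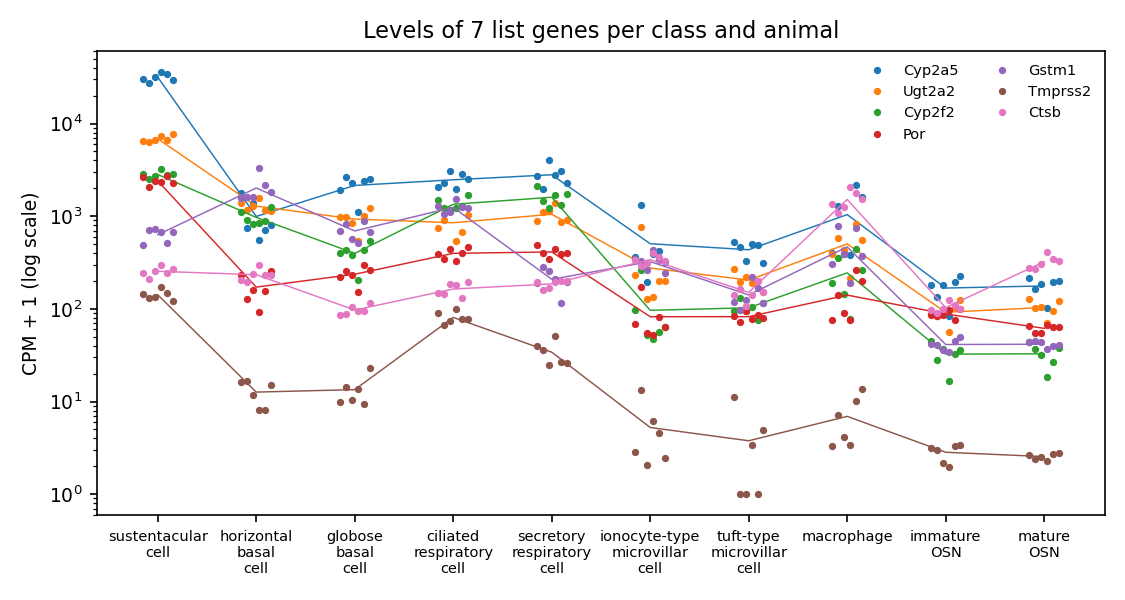
Levels (CPM plus 1, log scale) of 7 list genes in 10 cell classes, with 1 point per animal and lines through the means of 6 animals. Cyp2a5, Ugt2a2, Cyp2f2, Por and Tmprss2 peak in sustentacular cells, Gstm1 in horizontal basal cells and Ctsb in macrophages, of the 10 classes shown.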

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

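Of the tests in this part, those for a library difference shared by other cell classes and for free gland RNA were chosen before their results were seen, and those for blood, bone marrow, fewer epithelial cells, the depth of male 1 and other splits of the animals afterwards.

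Some leukocytes differed in share between the sexes. Neutrophils, monocytes or dendritic cells and B cells averaged 4.08-fold to 4.83-fold higher shares in males. Fewer epithelial cells from males would raise tissue macrophages too, and their male-to-female ratio was 1.04. Blood may have contributed: barcodes outside the MOE matrix with most UMIs from haemoglobin genes, 591 in all and a signal no comparison used, were 11.9-fold more frequent in males (1.58 ± 1.30% against 0.132 ± 0.0925%). The ratio was 6.39 without male 2 and 19.8 without female 2. Male 2 had the most such barcodes (3.05%) but the fewest neutrophils (62 cells) and B cells (23) of the males. Bone marrow stays open: precursor markers over all MOE cells were 5.96-fold higher in males (121.7 against 725.5 CPM), but Camp and Ngp, leading genes of the neutrophil cluster itself, carried the sum, which so restates the neutrophil share. Of the other markers Mpo (0.371 against 5.25 CPM), Elane (6.30 against 14.3), Prtn3 (7.26 against 20.7), Ltf (39.9 against 75.8), Igll1 (0.165 against 0.836), Vpreb1 (0.846 against 1.63), Dntt (0.0178 against 0.550) and Rag1 (0.00670 against 0.119) averaged higher in males, with overlapping groups for all but Mpo and Rag1, and Vpreb3 was level (10.9 against 10.7). At resolution 2 neutrophil precursors were 9.42-fold more frequent in males, and B cell precursors were 1 cell in females and 19 in males. A difference in dissection or a sex difference in leukocytes stays open and was not tested.

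The genes higher in female than male immediate neuronal precursors were the second pattern. The 37 such genes outside the sex-linked ones had positive medians in the other classes as well: the median over 10 other classes was 0.927 (0.680 to 1.05), against 1.12 in the precursors themselves. A difference between libraries that other cell classes share may therefore explain them better than the precursor state. For Bpifb9a and Bpifb9b, free gland RNA may be the source. The ratio of these genes differed between classes in 0 of 6 animals (by a chi-squared test, with 2 at an unadjusted p under 0.05). That result is weak, since reads assigned with error among these neighbouring genes could also keep the ratio level. The greater depth of male 1 was argued against, since 77 genes passed without it. A sex difference common to many cell types stays open, untested.

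Because 3 against 3 animals make only 10 splits, other splits are too few to settle chance for any sex comparison. The real split and the highest other gave 46 and 4 genes in immediate neuronal precursors, 16 and 5 in immature OSN, 15 and 4 in sustentacular cells, 12 and 2 in mature OSN, 6 and 4 in ciliated cells, 5 and 2 in globose basal cells, 5 and 4 in horizontal basal cells and 3 and 2 in tuft-type cells. In each of these, 1 of the 10 splits (the real one) gave as many. In ionocytes it was 2 of 10 (5 and 6 genes), in macrophages 2 (6 and 37), in secretory cells 3 (3 and 9), and for receptor abundance 10 (0 and 0). For cell numbers by edgeR it was 1 (3 and 1 classes). The macrophage split with 37 genes set females 1 and 3 with male 1 against the others, and its source was not tested. With 32 swaps of classes within animals, only the real grouping of class I against class II OSN gave as many genes (2266 and 254). That is 1 of 32, the smallest share these swaps can give, which argues against chance without excluding it. Between mature and immature OSN, the counts (1 of 32; 9948 and 1 genes) decide nothing, since clustering on the same expression values made the groups.

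In some values 1 animal lay far from the other 5, in 13 of 132 groups of 6 where the nominal rate of the test gives about 6.6. Those above the nominal number lay in levels per cell class (11 of 46, nominally 2.3), and paired differences gave no excess (2 of 73, nominally 3.65). Odorant-binding and related genes did so in macrophages of female 1 (Obp1a 367 CPM, Obp1b 583 CPM, Mup5 186 CPM) and male 1 (Obp2b 37.5 CPM), in ionocytes of female 2 (Lcn3 8.90 CPM, Lcn4 5.34 CPM) and in precursors of male 3 (Mup6 0.961 CPM). The last 3 rest on 5, 3 and 1 UMIs against 0 in the other animals, so counting alone can set them apart. The others were Tmprss4 in globose basal cells of male 1 (109 CPM), Gstm1 in horizontal basal cells of male 1 (3297 CPM), Aox2 in sustentacular cells of male 2 (952 CPM) and Ces1a in ciliated cells of male 2 (62.6 CPM). Each level was taken in the class with the highest mean, which 1 extreme animal can raise, and on the CPM scale. The nominal 2.3 is therefore not a chance level for them. The 2 paired ones, fewer than chance gives, follow. The log2 ratio of Nrp1 between mature and immature OSN was -2.01 in female 2, and that of Acsm4 between class I and class II OSN 3.72 in female 3.

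The difference between class I and class II OSN depended on sex for 26 genes by an edgeR interaction test, which was not repeated without single animals. For some of these genes 1 animal stood apart, though not as an outlier above. The log2 ratio of Stmn1 was -0.612 in female 2 against a mean of 0.480 in the others. That of Pcdh10 was -0.785 in female 3 against 0.545. Among list genes, the female minus the male difference was 0.84 for Nfix, 0.40 for the adhesion gene Kirrel2, 1.11 for Obp1a, 0.84 for Obp1b, 1.52 for Obp2a, 1.83 for Obp2b, -1.22 for the protocadherin gene Pcdh10, -0.97 for Stmn1 and -0.35 for Tmsb10. A further signal came from TAARs, which no comparison by receptor used. They were the assigned receptor of 185 MOE cells, 141 of them in the class of mature OSN, and of 0 cells in the OR_OSN matrix.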

How the results depend on the processing

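Alternatives on the 6% highest doublet scores, on unnamed clusters scored as a class, on horizontal basal cells as background, and without each animal for receptor matching, tied genes and list levels were chosen after seeing the data. Over all comparisons, 347 of 441 values under an alternative kept direction and side of the threshold or stayed within 1.5-fold of the count, 80 moved further, 4 became weaker, 4 stronger and 6 reversed. Of 2979 values of named genes 2733 kept their call, 204 lost it, 15 gained it, 27 moved and 0 reversed; 41 more had no adjusted p from DESeq2's own filter. Where no cause is given below, the cause was not tested.

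The counts of the sex comparison were the same with RLE factors, and all calls were kept. Without a low-count filter they rose to 173 in ciliated cells, 314 in globose basal cells, 453 in horizontal basal cells, 659 in immature OSN, 231 in immediate neuronal precursors, 202 in ionocytes, 209 in macrophages, 45 in mature OSN, 200 in secretory cells, 321 in sustentacular cells and 97 in tuft-type cells. All genes called with the filter were kept. DESeq2 gave 20 genes in globose basal cells, 28 in horizontal basal cells, 41 in immature OSN, 50 in immediate neuronal precursors, 12 in ionocytes, 13 in macrophages, 75 in mature OSN and 29 in sustentacular cells. Shared with the main calls were 16 of 46 in precursors, 4 of 15 in sustentacular cells, 2 of 5 in globose and 1 of 5 in horizontal basal cells; the others had no adjusted p from DESeq2's own filter, except 10 in precursors. With the shared replicate numbers as a block, 18 genes passed in ciliated cells, 12 in horizontal basal cells, 30 in immature OSN, 16 in ionocytes, 36 in macrophages, 8 in sustentacular cells and 6 in tuft-type cells. Whether these numbers pair animals stays open: in ciliated cells all 6 animals correlated best with their own number, in 4 classes none did, and correlations within a number lay between -0.14 and 0.21. Without the highest doublet scores ionocytes had 30 genes, at resolution 2 macrophages had 11, and with called doublets kept tuft-type cells had 5.

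Without 1 animal, the sex counts ranged from 3 to 39 in ciliated cells, 4 to 11 in globose basal cells, 5 to 38 in horizontal basal cells, 10 to 57 in immature OSN, 6 to 340 in immediate neuronal precursors, 3 to 83 in ionocytes, 5 to 27 in macrophages, 7 to 20 in mature OSN, 3 to 7 in secretory cells, 4 to 620 in sustentacular cells and 2 to 7 in tuft-type cells. The highest came without male 3 in all but macrophages and secretory cells (without male 2). Of named genes, 4 of 44 outside the sex-linked ones, 39 of 46 sex-linked, 28 of 28 between mature and immature OSN and 43 of 45 between class I and class II OSN passed in all 6 such fits.

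Between mature and immature OSN the count ranged from 9396 (without male 1) to 9895 (without female 1). Between class I and class II OSN it ranged from 1651 (without male 1) to 2136 (without female 1), was 931 with no animal block and 1222 with class II cells thinned, and with no block 1 list passed by camera with an estimated correlation. Receptor abundance gave 0 calls in every alternative and fit leaving out an animal, with 19 to 32 receptors at an unadjusted p under 0.05 in those fits. The number of classes apart by sex ranged from 4 (without female 2) to 8 (without male 3), and of classes called by edgeR from 1 (without male 1) to 3. With the replicate block, neutrophils (adjusted p = 0.0103) and B cells (0.0436) passed and monocytes or dendritic cells (0.163) did not.

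With an estimated correlation, the lists called by camera fell to 2 in ciliated, globose basal, horizontal basal and sustentacular cells, ionocytes, immature OSN and mature OSN, 1 in immediate neuronal precursors, macrophages and secretory cells, and 0 in tuft-type cells. They fell to 1 between mature and immature OSN and 0 between class I and class II OSN.

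Receptor matching ranged from 21.2% with a pseudocount of 1 to 70.2% with 10 cells per receptor, and from 35.9% (without male 2) to 39.5% (without female 3). Genes tied to the receptor numbered 342 with 10 cells per sex, and 526 (without male 2) to 565 (without male 3). The median r of synaptic vesicle genes fell from 0.155 to 0.0311 without female 2, now below random lists.

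Receptor genes per cell depended on thinning. Not thinned, the difference reversed for precursors minus globose basal cells (-0.413), mature minus immature OSN (-0.448), and immature (-0.0808) and mature OSN (-0.529) minus sustentacular cells, and was -0.913 for precursors minus sustentacular cells. Mature minus immature OSN was 0.152 at 1000 UMIs and 0.193 with 2 UMIs per receptor. In percent of cells with 2 or more, that difference was 0.556 at 1000 UMIs and 0.333 without the highest doublet scores, both reversed, -1.53 with 2 UMIs per receptor and -0.634 with called doublets kept. Not thinned, the percent differed from sustentacular cells by -16.4 in precursors, 6.93 in immature and 0.267 in mature OSN.

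Without 1 animal, receptor genes per cell differed by 0.0198 to 0.102 between precursors and globose basal cells, 0.789 to 0.826 between immature OSN and precursors and -0.00435 to 0.0278 between mature and immature OSN. Against sustentacular cells the ranges were -0.190 to -0.0450 (globose basal cells), -0.115 to -0.00475 (precursors), 0.691 to 0.808 (immature OSN) and 0.717 to 0.824 (mature OSN). In percent with 2 or more, the same 7 differences ranged from 2.24 to 4.14, 23.1 to 25.5, -2.23 to -1.64, -6.12 to -1.72, -3.87 to 0.559, 21.2 to 25.9 and 19.1 to 24.3. Genes higher than in mature OSN in every animal numbered 9 to 10 for coronavirus entry, 3 to 5 for odorant-binding proteins and 24 for xenobiotic metabolism.

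Depth differed between classes: the smallest sum, in tuft-type cells, was 193981 UMIs against 12961100 in mature OSN. The simulations covered no class rarer than the precursors.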

Other observations

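The test of neighbouring receptor genes and that of 2 cells in 1 droplet were chosen before their results were seen. The looks at TAAR neurons, precursors at resolution 2 and unnamed clusters were chosen afterwards.

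OSN with a TAAR, a receptor for volatile amines, made up 0.784 ± 0.261% of assigned mature OSN in the MOE matrix (0.858 ± 0.317% in females, 0.709 ± 0.231% in males). They expressed 12 TAAR genes, led by Taar6 (38 cells), Taar7b (27), Taar7d (26), Taar4 (23) and Taar7f (23). Of the 185 TAAR cells, 141 were in the class of mature OSN.

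An unnamed cluster of 460 cells (0.976 ± 0.197% of female and 1.06 ± 0.103% of male cells) was led by Tex15, Crabp1, Rcor1, Lmo1 and the neuronal differentiation gene Sox11. At resolution 2, a cluster of 649 cells also led by Tex15, Crabp1 and Rcor1 scored highest as immature OSN, with 6 of 6 markers raised 2-fold. It had 2 precursor markers among its 10 leading genes, so the stage of these cells stays open. After thinning to 2000 UMIs the cells of the 460-cell cluster held 1.91 ± 0.182 receptor genes, and 53.8 ± 4.77% held at least 2. This was 1.26 ± 0.182 more than immediate neuronal precursors and 0.445 ± 0.143 more than immature OSN, in 6 of 6 animals each (exact permutation p = 0.031, the smallest possible, not adjusted). Most of these receptors had 1 UMI. With 2 UMIs required per receptor, the value was 0.215, against 0.840 in immature OSN (lower in 6 of 6 animals), 0.172 in precursors and 0.259 in sustentacular cells, the background class. After thinning to 1000 UMIs it was 1.04, against 1.07 in immature OSN, so the excess over immature OSN did not hold in either setting. Without thinning the excess was present: the cluster held 4.82 to 6.58 receptor genes per cell over the 6 animals. Immature OSN then held 2.19 to 2.78 and sustentacular cells 2.29 to 3.38. Median UMIs per cell were lower in the cluster than in immature OSN in each animal.

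At resolution 2, a cluster of neutrophil precursors appeared, at 0.0501 ± 0.0108% of female and 0.472 ± 0.0936% of male cells (9.42-fold; edgeR log2 -3.14 ± 0.40, adjusted p = 0.00131; exact permutation p = 0.1, adjusted p = 0.3). B cell precursors were 1 cell in the females and 19 in the males (edgeR adjusted p = 0.0703). At resolution 1, other unnamed clusters included 2586 cells with sustentacular genes and Omp, 2435 led by Dcn, Gstm1 and Cyp1a2 (5.79 ± 0.331% in females, 4.96 ± 0.317% in males), 1718 led by Bpifb9a and 1672 by Bpifb3 and Obp2a. Of the 2586 cells, 84.5% carried both a receptor and Omp at 10 or more UMIs, and 21.3% were among the 6% highest doublet scores. Their UMIs were at the median 3.23 times the median of their library. Whether these droplets held 2 cells was not tested.

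In 5.36 ± 1.08% of mature OSN, a second receptor had at least 3 UMIs and over 1/3 of the UMIs of the first, in 1045 cells and 1013 different pairs, none of them in 5 or more cells. Random pairings within animals gave 1035 ± 2.99 different pairs, so pairs recurred more often than random pairing gives, and the reason was not tested. If neighbouring receptor genes were expressed together, such pairs would share a genomic cluster more often, but 5.54% did against 6.01 ± 0.723% in random pairings, which argues against it. Droplets with 2 cells may account for the second receptor, and the UMI ratio to other mature OSN, 1.47 ± 0.238, lay between that of 1 and 2 cells and leaves this open. Cells that meet at random would not give the recurrence of pairs, but the recurrence lay in part within single animals. Many recurring pairs, such as Olfr1018 with Olfr12, had their 2 cells in 1 animal, and others, such as Olfr1030 with Olfr1507, in 2. A source within single libraries was not tested. No biological explanation was tested beyond these.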
